A study of Mus musculus with 3 samples.

How the data were processed

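Round spermatids, the haploid germ cells that follow meiosis, were sorted by fluorescence-activated cell sorting on Hoechst staining from testes of 28-day-old C57BL/6 mice, per the labels' protocols. Messenger RNA libraries were prepared with the VAHTS mRNA-seq V3 kit from total RNA of wild-type, MiwiΔIns and MiwiR371W mice, 1 library per genotype. The labels do not say how many animals were pooled for a library, nor whether the libraries keep the strand of the RNA.

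The authors deposited a single table of genes by libraries, whose values are a signal that is normalised to transcript length and library size. Trim Galore 0.5.0, STAR and RSEM are named as tools and mm10 (GRCm38) as the genome, per the submitters' processing notes. Tool settings, roles and the gene annotation are not given in the sources used here. Whether the deposited signal is FPKM or TPM is also not given, and the values left this open. Within a library the units differ only by a constant factor, but that factor can differ between libraries. Ratios between libraries thus depend on the unit, and no scaling of the full table to equal sums was run. The median and upper quartile scalings given below adjust for such a factor. Sums of the values were 647897 in wild type, 697804 in MiwiΔIns and 630809 in MiwiR371W. The table held 17946 genes with identifier, symbol and gene type, of which 15497 were protein-coding, 765 pseudogenes, 732 lincRNA genes, 571 antisense genes and 341 processed transcripts. Every gene had a value above 0 in all 3 libraries, with a lowest value of 0.01, so a gene listed at 0 in any library was not analysed here. No repeat element was named among the genes, so transposons were not analysed here. The design fixed for the work assumed TPM or FPKM values, and its rules were applied to the deposited values unchanged.

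Gene positions, transcript lengths and GC contents came from GENCODE M21 (GRCm38) and were matched on the gene identifier without its version for 17673 genes (98.5%). Length and GC were medians over a gene's transcripts. For 40 gene symbols the table held more than 1 gene.

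The depth behind the values was estimated from single-transcript genes longer than 2500 nt. Their low values, multiplied by effective transcript length, clustered on steps, taken as what 1 fragment was worth. The step was 0.075 value × kb in wild type, 0.07 in MiwiΔIns and 0.0915 in MiwiR371W. The mean distance of values from a whole number of steps was 0.132, 0.155 and 0.119 steps, against 0.25 for values without steps. A value of 5 in a transcript with 1 kb of effective length thus rested on about 67, 71 and 55 fragments. At that level counting error alone gave a log2 ratio an SD of 0.25 between 2 libraries of the wild-type depth, 0.24 at the depth of MiwiΔIns and 0.28 at that of MiwiR371W. On simulated steps of 0.08 the search returned 0.081. Counting error does not include differences between animals, sorts or library preparations.

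With 1 library per genotype no statistical test was possible, and no p-value or standard error across genes was computed. Ratios were computed as log2((x + 1)/(y + 1)), where the pseudocount of 1 understates changes of low genes. A gene was counted as higher or lower when its value differed at least 2-fold on this scale and was at least 5 in the higher library. Such counts compare these libraries and have no replicate check. Comparisons were MiwiΔIns against wild type, MiwiR371W against wild type and MiwiR371W against MiwiΔIns.

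Genes named in the text followed a rule. Piwil1, the gene that encodes MIWI, came first. Then came the 8 largest increases and 8 largest decreases of each mutant against wild type, and the 5 each way between the mutants, among genes past the size rule with at least 10 in the higher library. Predicted genes, clone names and pseudogenes were left out. Up to 5 genes each way that were past the rule in both mutants were added, ordered by the smaller of the 2 log2 ratios. The minimum of 10 was applied to these in both comparisons, which the fixed rule did not spell out. From each gene list up to 2 members each way past the rule were named, or the 2 most highly expressed members where none passed. A gene that met this rule is not reported here. Any other gene is said to have been chosen after its values were seen.

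The 22 gene lists covered the piRNA pathway, haploid transcription regulators, late spermiogenesis and chromatin condensation, the acrosome, flagellum and axoneme, the histone to protamine transition, translation regulators of the male germline, mRNA deadenylation and decay, ribosomal protein genes, mitochondrially encoded mRNAs, the unfolded protein response, immediate early and heat shock genes, p53 and apoptosis, the interferon response, transposon families, and 7 lists of cell type markers. The marker lists were for meiotic prophase spermatocytes, spermatogonia, Sertoli cells, Leydig cells, macrophages, peritubular and endothelial cells, and erythroid cells. A member was measured when its mean over the 3 libraries was at least 1. The median log2 ratio of a list was placed among the medians of 10000 random lists of equal size matched on mean expression in 20 bins. A list with at least 3 measured members was described as standing apart when this percentile was under 2.5 or over 97.5. No transposon family and no erythroid marker was measured, which left 20 lists and 60 list comparisons.

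The overlap of both mutants' gene counts was set beside the overlap of independent lists and beside 100 simulated sets of 3 unchanged libraries, because both mutants were compared with a single wild-type library. The simulated spread came from the difference between the mutants and therefore contains any true difference between them. Copies of genes were searched with blastn (BLAST+ 2.17.0) among GENCODE M21 transcripts, at 95% identity over at least 80% of the longest transcript. Exons of other genes that overlap those of the named genes were taken from the same annotation. Genes named only from a gene list, such as Rpl10 and Rps3a2, were not part of these 2 checks. Shares were given with exact Clopper-Pearson 95% intervals. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

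Size rule, gene lists, naming rule and the alternatives in pseudocount, minimum, fold threshold, scaling and list membership were fixed before the data were examined. A correction that removed the trend of each library with GC content and transcript length (20 bins, 3 rounds, fitted on genes with a mean of at least 5), and a restriction to protein-coding genes with transcripts of at least 500 nt, were added after the data had been seen. The procedures were tested on simulated data of 17946 genes for MiwiR371W against wild type, with 200 genes changed. Of these, 45.0% of the 2-fold and 94.0% of the 3-fold changes were recovered, and 1 unchanged gene passed the rule. A simulated shift of the acrosome list was placed at percentile 0, and 1.8% of the unshifted list comparisons fell outside the limits. The simulated noise was independent between genes and narrower than the spread of the real log2 ratios to wild type (SD 0.4 for MiwiΔIns and 0.47 for MiwiR371W). These rates therefore do not measure false calls in the deposited libraries. For MiwiΔIns against wild type, a GC trend simulated on 8186 genes (Spearman rho −0.53) was removed by the correction.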

Results

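The transcriptomes of sorted round spermatids from wild-type mice and from mice with either of 2 alleles of Miwi, named MiwiΔIns and MiwiR371W, were compared to examine messenger RNA levels. Miwi (Piwil1) encodes a PIWI protein that binds piRNAs in meiotic and postmeiotic male germ cells. Each genotype was represented by 1 library, so no difference below has a replicate check, and each describes these libraries. Expression is given in the deposited length- and library-normalised value. The MiwiΔIns and MiwiR371W libraries had 1.07 and 0.82 times as many fragments per unit of value as wild type. Of 17946 genes, 12567 had a mean value of at least 1.

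Piwil1 itself (ENSMUSG00000029423.6, GRCm38 chromosome 5, 128702524 to 128755474, plus strand) had a value of 20.3 in wild type, 23.2 in MiwiΔIns and 23.5 in MiwiR371W. Its log2 ratios to wild type were 0.19 and 0.20, neither past the size rule. A gene-level value does not show which allele was transcribed, so it does not check the genotypes. Transcripts of spermatid chromatin proteins were abundant in all 3 libraries. The protamine Prm1 was at 4043 in wild type, 5776 in MiwiΔIns and 4989 in MiwiR371W, and the transition protein Tnp2 at 4085, 5167 and 4265.

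In the MiwiΔIns library, 111 genes were higher and 65 lower than in wild type, of 8550 genes with a value of at least 5 in either library. Of these, 60 higher and 35 lower genes were protein-coding, and 67 and 39 had predicted, clone or pseudogene names. Among 8898 genes with a value of at least 5 in any library, 8011 were protein-coding and 1706 had such names. Il6st, the shared signal-transducing receptor of interleukin-6 family cytokines, was higher, at 12.1 against 1.84 (log2 2.21). Mms19, a factor of cytosolic iron-sulfur protein assembly, was at 18.8 against 5.40 (log2 1.63). The retromer subunit Vps29 was at 68.5 against 28.9 (log2 1.22). Vps39, a subunit of the lysosomal HOPS tethering complex, was lower, at 5.40 against 16.2 (log2 −1.43).

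Other genes named by the rule as higher in MiwiΔIns were the actin capping subunit Capza2 (log2 1.45), the RNA polymerase subunit Polr2k (1.32), the signal peptidase subunit Sec11c (1.28), the ribosomal protein gene Rpl22 (1.17) and Pigk, a subunit of the GPI transamidase (1.16). Lower ones were Plac9b, at 2.64 against 23.7 (log2 −2.76), TUG1_3, at 10.4 against 70.4 (−2.65), the RNA polymerase II subunit Polr2b (−1.37), the unconventional myosin Myo18a (−1.24), the organic anion transporter Slco6b1 (−1.22) and the deubiquitinase Otud7a (−1.19). With the GC and length trend removed, Rpl22 (0.94), Myo18a (−0.93) and Otud7a (−0.96) lost the call. With a pseudocount of 5 it was lost by Capza2 (0.97), Polr2k (0.86), Sec11c (1.0 after rounding), Pigk (0.89), Polr2b (−0.87), Myo18a (−0.88), Slco6b1 (−0.78) and Otud7a (−0.85). TUG1_3 is a 236 nt annotated fragment within Tug1, and Plac9b has near-identical copies (Plac9a and Gm9780), so the division of their reads is uncertain. Exons of Mms19, Vps29, Pigk and Polr2b overlap a gene on the opposite strand.

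Ribosomal protein genes and mitochondrially encoded mRNAs were higher as groups in MiwiΔIns. Of 79 measured ribosomal members, 70 had a positive log2 ratio, with a median of 0.32 (percentile 100 among matched random lists). Past the size rule 3 members were higher and 0 lower. These were Rpl10, at 6.45 against 2.06 (log2 1.28), Rpl22, at 48.8 against 21.1, and Rpl10a, at 24.99 against 12.0 (log2 1.0). Rpl10a lost the call under all 3 rescalings, at 0.93 to 0.97, and with a pseudocount of 5, at 0.82, where Rpl10 was also lost (0.70). Rpl22 lost it with the GC and length trend removed (0.94). All 12 measured mitochondrially encoded mRNAs had positive log2 ratios, with a median of 0.39 (percentile 99.89) and 0 past the rule. The ATP synthase subunit transcript mt-Atp8 was at 5187 against 2613 (log2 0.99), and the cytochrome oxidase transcript mt-Co2 at 2803 against 1687 (0.73). At 204 nt, mt-Atp8 is shorter than the length subtracted in the depth estimate (300 nt in wild type, 250 nt in MiwiΔIns), so its length-normalised value is uncertain. Sertoli cell markers had a median of −0.25 over 9 members (percentile 2.3), 0 of them past the rule. This list no longer stood apart with a pseudocount of 5 (percentile 5.40) or in the 3 rescalings (2.99, 3.22 and 3.24). Clusterin (Clu) was at 11.8 against 19.6 and Defb19 at 8.45 against 9.44.

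Gene groups of the spermatid programme did not stand apart in MiwiΔIns, and none of their members passed the rule. The median was 0.13 for late spermiogenesis (39 members, percentile 81.03), 0.12 for the acrosome (29 members, 81.79), 0.08 for flagellum and axoneme (37 members, 72.61) and 0.08 for haploid transcription regulators (14 members, 54.41). Transcripts of Spz1 and Crem, both haploid transcription factors, had log2 ratios of 0.22 and 0.25. The acrosomal genes Crisp2 and Acrbp had 0.35 and −0.03, and the axonemal genes Meig1 and Rsph1 0.29 and 0.57. The piRNA pathway had a median of 0.11 (27 members, percentile 82.26), with Mael at 0.26 and the helicase Ddx25 at 0.17.

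Other lists in MiwiΔIns also lay within the limits. Medians were −0.02 for the histone to protamine transition (22 members, percentile 25.48), 0.06 for germline translation regulators (18 members, 49.66), −0.04 for mRNA deadenylation and decay (33 members, 10.84), 0.19 for the unfolded protein response (17 members, 95.55) and −0.08 for immediate early and heat shock genes (18 members, 10.31). They were 0.13 for p53 and apoptosis (9 members, percentile 79.02) and −0.11 for the interferon response (4 members, 28.72). Among markers of other cells they were 0.05 for spermatocytes (25 members, percentile 58.54), 0.01 for spermatogonia (10 members, 51.89), −0.02 for Leydig cells (3 members, 40.58), −0.01 for macrophages (4 members, 47.93) and −0.11 for peritubular and endothelial cells (4 members, 22.27). Erythroid markers had 0 measured members. The meiotic chaperone gene Hspa2 had a log2 ratio of −0.53 and the synaptonemal complex gene Syce1 0.22.

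Log2 ratios in MiwiΔIns fell with the GC content of the transcript (Spearman rho −0.43 across 8186 genes, which are not independent replicates). The median ranged from 0.16 in the fifth of genes with the lowest GC to −0.20 in the fifth with the highest. With the GC and length trend removed, the split of 111 higher and 65 lower genes became 74 and 72, the ribosomal median 0.23 (percentile 100) and the mitochondrial median 0.25 (99.65). The late spermiogenesis median was then 0.15 and stood apart (percentile 99.07).

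**Figure D1:**
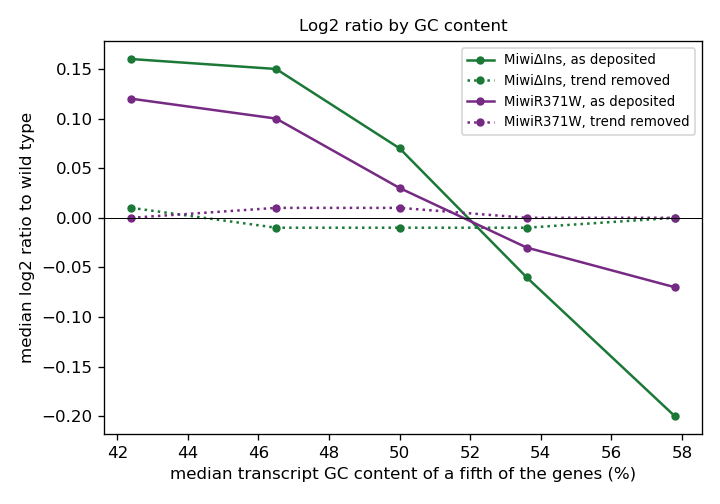
Median log2 ratio to wild type (vertical axis) in 5 equal groups of genes ordered by transcript GC content (horizontal axis, percent), for genes with a mean value of at least 5. Solid lines show the deposited values and dotted lines the values after removal of the GC and length trend. For MiwiΔIns the deposited medians run from 0.16 to −0.20 and for MiwiR371W from 0.12 to −0.07.

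In the MiwiR371W library, 127 genes were higher and 161 lower than in wild type, of 8719 genes with a value of at least 5 in either library. Protein-coding genes made up 91 and 103 of them, and 45 and 88 had predicted, clone or pseudogene names. Ube4b, a ubiquitin chain elongation factor, was higher, at 109.5 against 24.9 (log2 2.09), and the ribosomal protein gene Rpl10a was at 67.1 against 12.0 (2.39). Igfbp7, a secreted insulin-like growth factor binding protein, was at 11.0 against 2.08 (log2 1.96). Cdh2, which encodes N-cadherin, was lower, at 1.75 against 17.3 (log2 −2.73), as was the actin-nucleating formin Fmn1, at 30.1 against 102 (−1.72). Bcl2l11, which encodes the pro-apoptotic protein BIM, was at 4.98 against 20.6 (log2 −1.85).

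Erdr1, a gene of the pseudoautosomal region, had the largest increase named by the rule, at 20.2 against 0.19 (log2 4.15), and was at 6.03 in MiwiΔIns. Also higher in MiwiR371W were Speer4c, of a multi-copy testis family (log2 2.17), Tmem254c (1.74), the vesicle trafficking gene Sec22c (1.5) and Mms19 (1.37, and 0.99 with a pseudocount of 5). Also lower were TUG1_3 (log2 −2.84), the thymosin gene Tmsb15b1 (−2.37), the potassium channel subunit Kcnab2 (−1.97) and the tubulin gene Tubb6, at 13.1 against 42.7 (−1.64). Speer4c, Tmem254c and Tmsb15b1 have near-identical copies, and exons of Kcnab2 and Tmsb15b1 overlap other genes on their own strand. Exons of Speer4c, Ube4b, Fmn1, Rpl10a and Igfbp7 overlap genes on the opposite strand, so reads of those partners cannot be separated without strand.

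Acrosome transcripts were lower as a group in MiwiR371W. Of 29 members, 21 had a negative log2 ratio, with a median of −0.23 (percentile 0.63). The sperm acrosome membrane protein gene Spaca4 was lower, at 119 against 239 (log2 −1.0), and was the member past the size rule. It lost the call with a pseudocount of 5 (−0.98), without mitochondrial and top 50 genes (−0.95) and with the GC and length trend removed (−0.91). Among members chosen after their values were seen, Spaca1 was at 191 against 280 (log2 −0.55), Acrv1 at 331 against 460 (−0.47), and the sperm-egg fusion gene Izumo1 at 63.4 against 98.7 (−0.63). The protease gene Acr had a log2 ratio of −0.16 and Zpbp2 0.17. Late spermiogenesis genes had a median of −0.13 (39 members, percentile 12.56), with Prm1 at 0.30 and Tnp2 at 0.06. Medians were −0.15 for haploid transcription regulators (14 members, percentile 13.17; Spz1 −0.18, Crem −0.15) and 0.08 for flagellum and axoneme (37 members, 97.18; Meig1 −0.09, Rsph1 0.53).

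Transcripts of the piRNA pathway were slightly higher as a group in MiwiR371W, with a median of 0.25 over 27 members (percentile 99.58), 21 positive and 0 past the rule. Mael had a log2 ratio of 0.23 and Ddx25 0.11. Chosen after their values were seen, Piwil2, which encodes MILI, was at 12.9 against 7.37 (log2 0.73), and Mov10l1, the helicase needed for piRNA biogenesis, at 9.32 against 5.23 (0.73). All 12 mitochondrially encoded mRNAs were positive, with a median of 0.46 (percentile 100) and 0 past the rule. Among them mt-Atp8, with the same caution on its length, was at 4126 and mt-Co2 at 2422, with log2 ratios of 0.66 and 0.52. Both mutants were compared with the same wild-type library, so their mitochondrial medians are not independent. Between the mutants the mitochondrial median was 0.04 (percentile 94.91). Ribosomal protein genes had a median of 0.01 (79 members, percentile 90.63; 0.04 and 99.83 with the GC and length trend removed), with 2 members higher, Rpl10a and Rps3a2 (log2 1.64, and 0.78 with a pseudocount of 5). Rps3a2 was not searched for near-identical copies.

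Immediate early and heat shock genes had the highest list median in MiwiR371W, 0.54 over 18 members (percentile 100), with 15 positive and 3 past the rule. Fos was at 5.72 against 1.24 (log2 1.58), the small heat shock protein gene Hspb1 at 8.85 against 3.41 (1.16), and Junb, chosen after its value was seen, at 5.44 against 1.89 (1.16). With a pseudocount of 5, Fos (0.78), Hspb1 (0.72) and, by its values, Junb lost the call. Limited to members with a mean of at least 5, the median was 0.22 (percentile 96.09) and no longer stood apart. Unfolded protein response genes had a median of 0.34 over 17 members (percentile 99.96), 14 positive and 0 past the rule. The endoplasmic reticulum chaperone Hsp90b1 was at 319 against 204.0 (log2 0.64) and calreticulin (Calr) at 368 against 298 (0.30). Translation regulators had a median of 0.12 over 18 members (percentile 97.78), which was 80.65 with the GC and length trend removed and on the upper limit with median scaling. Their most abundant members, Ybx2 and Ybx1, had log2 ratios of −0.12 and −0.14.

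Markers of other cells did not stand apart as groups in MiwiR371W, except Sertoli markers with a pseudocount of 5 (median −0.17, percentile 1.5). The spermatocyte median was 0.13 (25 members, percentile 91.22; Hspa2 −0.16, Syce1 0.12), the spermatogonial median 0.22 (10 members, 81.58; Dazl 0.50, Id4 0.21) and the Sertoli median −0.29 (9 members, 2.58). Leydig markers had a median of −0.07 (3 members, percentile 27.28; Scarb1 −0.59), macrophage markers 0.30 (4 members, 81.33; Apoe 0.97) and peritubular and endothelial markers 0.32 (4 members, 89.55). Single somatic markers were higher at low levels. Vimentin (Vim) was at 6.10 against 1.55 (log2 1.48) and smooth muscle actin (Acta2) at 5.53 against 1.01 (1.70), and neither passed the rule with a pseudocount of 5 (0.76 and 0.81). The more abundant markers Actg2, Scarb1 and Clu were at 147, 26.5 and 13.95 against 257, 40.4 and 19.6, none past the rule. The remaining medians were 0.19 for p53 and apoptosis (9 members, percentile 77.15; Mdm2 −0.10, Zmat3 0.82), −0.11 for the interferon response (4 members, 21.37; Ifi27 0.95), 0.14 for mRNA deadenylation and decay (33 members, 94.89; Pabpc1 0.04) and 0.08 for the histone to protamine transition (22 members, 78.0). In the last list 1 member was higher, the testis histone gene Hist1h2aa, at 5.56 against 1.94 (log2 1.16, and 0.61 with a pseudocount of 5). Without mitochondrially encoded genes and the 50 most abundant genes, and rescaled, the split of 127 higher and 161 lower genes became 154 and 127.

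**Figure D2:**
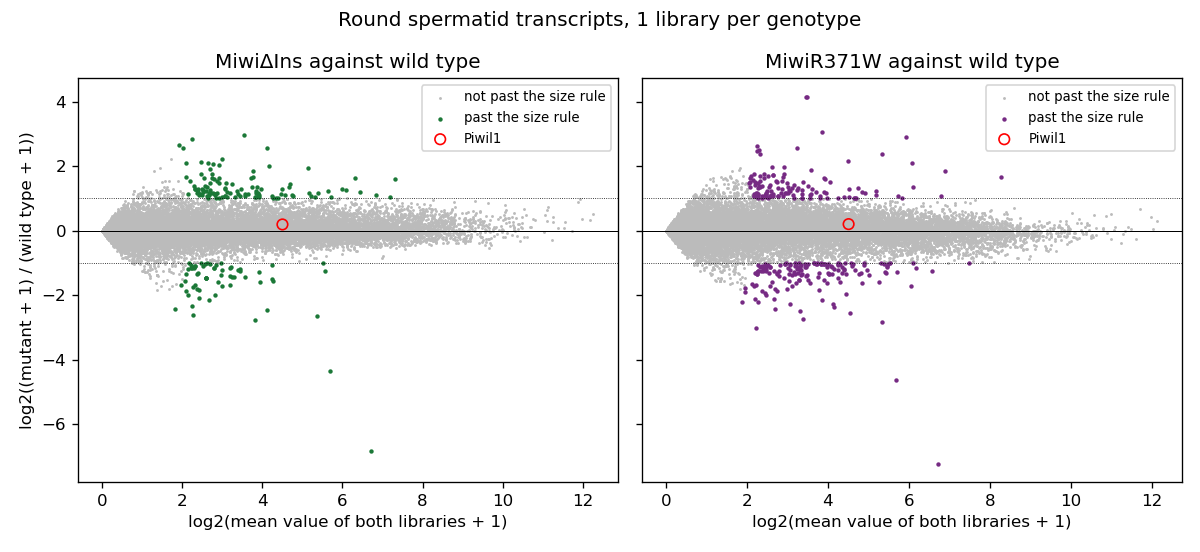
Log2 ratio of each mutant library to wild type (vertical axis) against the log2 of the mean value of both libraries plus 1 (horizontal axis), 1 point per gene. Coloured points are the genes past the size rule, 111 higher and 65 lower in MiwiΔIns and 127 higher and 161 lower in MiwiR371W, and the red circle is Piwil1 (log2 0.19 and 0.20). Dotted lines mark 2-fold ratios.

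**Figure D3:**
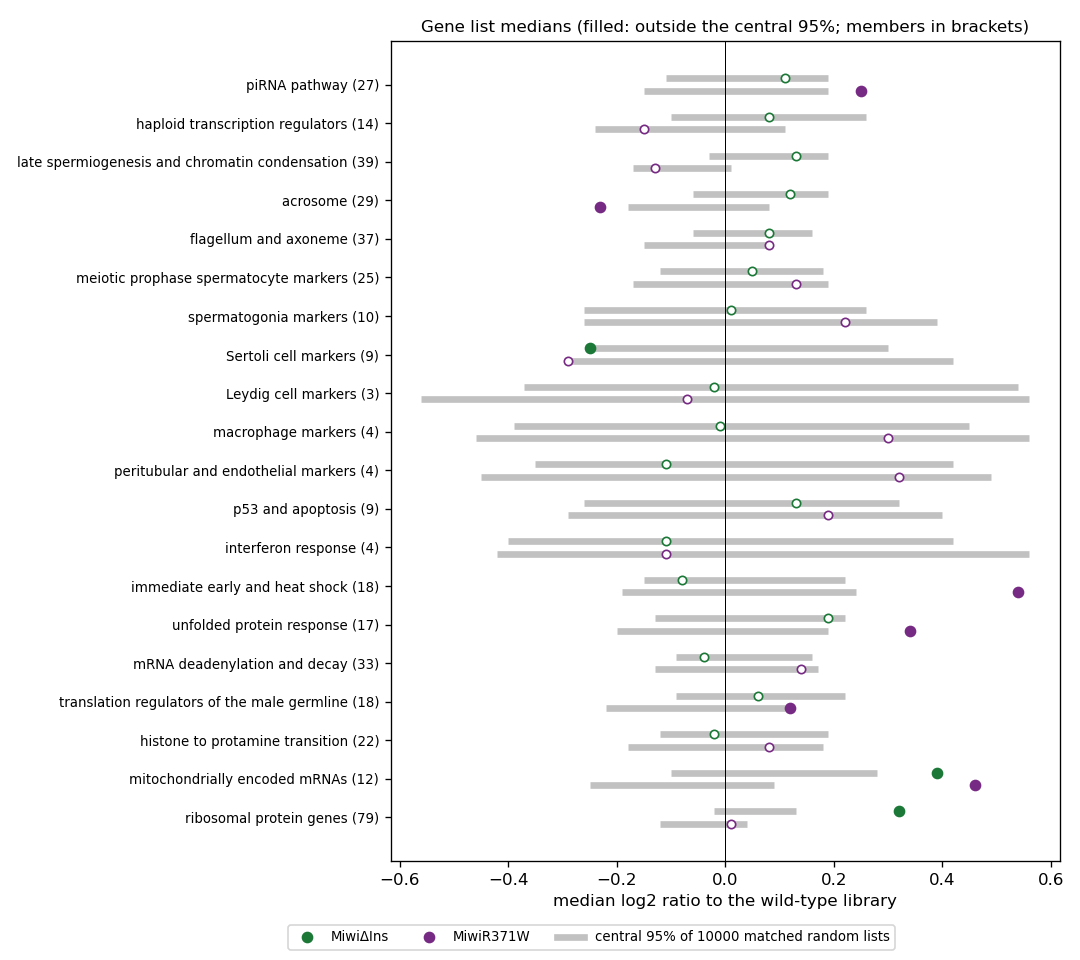
Median log2 ratio to wild type (horizontal axis) of 20 gene lists, for MiwiΔIns and MiwiR371W, with the number of measured members in brackets. Grey bars span the central 95% of medians of 10000 random lists matched on expression, and filled points lie outside it. The acrosome list is at −0.23 in MiwiR371W and the ribosomal list at 0.32 in MiwiΔIns.

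The mutant libraries differed from each other by more genes than either differed from wild type. In MiwiR371W 111 genes were higher and 281 lower than in MiwiΔIns, of 8744 genes. Protein-coding genes made up 81 and 178 of them, and 44 and 173 had predicted, clone or pseudogene names. Higher in MiwiR371W were Ube4b, at 109.5 against 19.4 (log2 2.44), Vps39, at 33.5 against 5.40 (2.43), Myo18a, at 30.1 against 5.45 (2.27), Plac9b (2.09) and Igfbp7 (2.05). Lower were Fmn1, at 30.1 against 169 (log2 −2.45), Cdh2, at 1.75 against 13.3 (−2.38), Il6st (−2.04), Tmsb15b1 (−2.00) and Riiad1, at 43.8 against 145 (−1.71). Exons of Riiad1 overlap those of Celf3 on the opposite strand.

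Of the gene groups, acrosome transcripts were lower in MiwiR371W than in MiwiΔIns, with a median of −0.29 over 29 members (percentile 1.97) and 22 negative. The member past the rule, Fam209, chosen after its value was seen, was at 297 against 620.1 (log2 −1.06). Ribosomal protein genes had a median of −0.28 (percentile 0.02), with 63 of 79 members negative, while Rpl10a and Rps3a2 were higher (log2 1.39 and 1.71). Immediate early and heat shock genes had a median of 0.55 (percentile 100), with 17 of 18 members positive, and 0.28 (percentile 98.95) for members with a mean of at least 5. Fos (log2 1.81) and Hspb1 (1.10) passed the rule, as did Junb (1.17). Late spermiogenesis genes had a median of −0.27 (percentile 5.59), and the piRNA pathway 0.17 (97.41), both within the limits. With the GC and length trend removed, the late spermiogenesis median was −0.31 and stood apart (percentile 1.62). Without mitochondrially encoded genes and the 50 most abundant genes, and rescaled, the median of all genes moved to 0.14 and the split of 111 higher and 281 lower genes became 162 and 195. The ribosomal median was then −0.15 (percentile 0.03) and the acrosome median −0.20 (percentile 1.0).

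Relative to wild type, 22 genes were higher and 25 lower in both mutants. Named by the rule as higher in both were Mms19, Pigk (8.16 in wild type, 19.4 and 19.9 in the mutants), Dydc2 (16.6, 36.2 and 39.0) and Rpl10a (12.0, 24.99 and 67.1). Lower in both were TUG1_3 (70.4, 10.4 and 8.98) and Otud7a (14.2, 5.64 and 5.87). The minimum of 10 left other annotated genes unnamed. Among those, chosen after their values were seen, Scgn (2.37, 7.15 and 6.88) was higher in both. Mamdc4 (7.4, 0.36 and 0.03) and Dok2 (6.91, 0.57 and 0.71), chosen likewise, were lower in both. In MiwiΔIns the call was lost by Dydc2 and Otud7a with the GC and length trend removed (log2 0.83 and −0.96) and with a pseudocount of 5 (0.93 and −0.85). A pseudocount of 5 also took it from Otud7a (−0.82), Pigk (0.92) and Mms19 (0.99) in MiwiR371W and from Pigk (0.89) and Rpl10a (0.82) in MiwiΔIns. Rescaling took it from Rpl10a in MiwiΔIns (0.93 to 0.97). Gm1848, a pseudogene near-identical to Atp1b3 and chosen after its values were seen, was at 208 in wild type, 0.82 in MiwiΔIns and 0.39 in MiwiR371W. Independent lists of these sizes among 8371 genes would share 1.68 higher and 1.25 lower genes. Simulated unchanged libraries with a shared control shared 44 higher (28 to 61) and 69.2 lower (50 to 89). The observed overlaps lay below both ranges. The simulated spread came from the difference between the mutants and so overstates the noise by any true difference. The simulated mean of lower genes exceeded the 65 genes lower in MiwiΔIns, so the observed overlap could not have reached it. Part or all of the number of shared genes may come from the shared control. The correlation of log2 ratios across 12567 genes was 0.35 (0.5 simulated) and the covariance 0.065 (0.123 simulated), and the single control could not be split.

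Against both other libraries at once, MiwiR371W had 60 genes higher and 76 lower, MiwiΔIns 42 and 11, and wild type 25 and 22. Of genes with a mean of at least 1, 97.8% lay within 2-fold between MiwiΔIns and wild type, 96.4% between MiwiR371W and wild type and 95.3% between the mutants. The MiwiR371W library had the fewest fragments per unit of value, so its low values were the least precise.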

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

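All explanations below were weighed on these 3 libraries alone. Tests of dilution by other cells, of the GC trend and somatic RNA for the immediate early genes, and of the pair Gm1848 and Atp1b3 were chosen after the result was seen, and the criterion for dilution was revised with its values known. Under the earlier criterion, the 35.9% of late spermiogenesis genes with a positive ratio had counted against dilution.

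Opposite moves past the size rule in the mutants singled out 3 genes, and the difference between the mutants was not tested for want of replicates. Vps39 had log2 ratios to wild type of −1.43 in MiwiΔIns and 1.0 in MiwiR371W. Myo18a had −1.24 and 1.03. The MiwiR371W ratios of both sat near the threshold. In that library, Vps39 was at 0.96 and 0.98 with median and upper quartile scaling, and Myo18a at 0.99 with median scaling and with the GC and length trend removed. Myo18a in MiwiΔIns was at −0.93 with that trend removed, and a pseudocount of 5 left Vps39 at 0.86 in MiwiR371W and Myo18a at −0.88 and 0.87. The clone-named 1700023C21Rik had 1.12 and −2.29.

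Acrosome transcripts were lower in MiwiR371W (median −0.23, percentile 0.63). A GC and length trend between libraries is argued against, since after its removal the median was −0.35 and the percentile 0, as is low depth, by a median of −0.35 for the 22 members with a mean of at least 100. Dilution of spermatid RNA by other cells cannot be told apart: the late spermiogenesis median (−0.13) lay 0.10 above the acrosome median, within the combined uncertainty from both lists' random limits (0.16), and spermatocyte and spermatogonial medians of 0.13 and 0.22 were within their limits. Against dilution speak a flagellum and axoneme median of 0.08 (percentile 97.18) and Prm1 and Prm2 at 0.30 and 0.41, Prm2 chosen after its value was seen. Other values go the other way. Of 39 late spermiogenesis genes 25 were negative, with Tnp2 at 0.06, and the haploid regulators had a median of −0.15 (percentile 13.17). The 542 genes with RIKEN clone names, described under other observations, had a median of −0.15 (percentile 0). The piRNA pathway list was higher (median 0.25, percentile 99.58). Which of these lists are limited to spermatids, or to earlier germ cells, was not measured here. Open hypotheses, not tested, are an effect of the MiwiR371W allele on these transcripts, a difference in developmental step between the sorted spermatids, and variation between sorts.

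Immediate early and heat shock transcripts were higher in MiwiR371W (median 0.54, percentile 100), but members with a mean of at least 5 had a median of 0.22 within the limits (percentile 96.09), so the pattern rests largely on members at low values. Removal of the GC and length trend left the median at 0.49 and the percentile at 100, which argues against that trend as the whole cause. RNA of somatic testis cells, which the Hoechst gate would be meant to remove, cannot be told apart: the highest percentile among 4 somatic lists was 89.55, and those lists held few measured members. Vim and Acta2 reached 6.10 and 5.53, and all 4 measured macrophage markers had positive ratios, whereas 6 of 9 Sertoli markers had negative ones. The more abundant markers Actg2, Scarb1 and Clu had lower values than in wild type (147, 26.5 and 13.95 against 257, 40.4 and 19.6). Whether these transcripts came from somatic cells was not measured. In wild type Actg2 was at 257 while Acta2 was at 1.01, so the fall of Actg2 does not bear on somatic RNA. Actg2 was the 1 negative member of 4 in the peritubular and endothelial list, whose percentile (89.55) was not computed without it. Scarb1 was at 40.4 in wild type with 3 of 14 Leydig markers measured, so its source is open as well. A stress response during cell dissociation, or one of the genotype, was not tested.

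Genes at least 2-fold from wild type in both mutants were the remaining pattern. Shared reads with near-identical copies remain an undecided candidate explanation for part of it. Of 46 such genes 26.1% (12, exact 95% interval 14.3 to 41.1) had a copy, against 11.7% of 230 random genes matched on level and length (7.9 to 16.6). The intervals overlap, and the random genes left out any gene past the size rule and were not matched on gene type. The 12 include TUG1_3, whose copy is the Tug1 gene it lies within, and Metazoa_SRP genes with identical values. A simple transfer of reads is argued against for Gm1848, since Atp1b3 gained at most 9.4% of its loss, although a copy at 0 in any library was not analysed here. Flanking DNA of another background around the edited Piwil1 locus cannot be told apart, with 1 of 46 genes (2.2%, interval 0.1 to 11.5) within 20 Mb against 3.42% of all genes. A wild-type animal that carried other copies of such sequences could also give these values, and no test here bears on that. Variation of the single wild-type library, which both ratios share, may account for part or all of the number of shared genes and could not be separated.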

How the results depend on the processing

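No paired analysis was possible because each genotype had 1 library and no test was made. Counts are given in the order MiwiΔIns against wild type higher and lower, MiwiR371W against wild type higher and lower, MiwiR371W against MiwiΔIns higher and lower, genes past the rule in the same direction in both mutants, then genes apart from both other libraries in MiwiΔIns, MiwiR371W and wild type. Main counts were 111, 65, 127, 161, 111, 281, 47, 53, 136 and 47. At 1.5-fold they were 610, 217, 655, 722, 581, 1098, 241, 346, 705 and 241. At 4-fold they were 11, 10, 12, 16, 16, 16, 9, 5, 9 and 9. Without a minimum, and equally with a minimum of 1, they were 176, 126, 257, 243, 248, 390, 93, 91, 217 and 93. A minimum of 20 gave 29, 12, 29, 60, 24, 153, 9, 13, 44 and 9. A pseudocount of 5 gave 33, 17, 30, 54, 31, 143, 16, 16, 42 and 16. These follow from how strict each setting is. A pseudocount of 0.1 moved only the MiwiΔIns genes apart by more than 1.5 times, to 80. Restriction to protein-coding genes of at least 500 nt, chosen after seeing the data, gave 49, 25, 82, 86, 72, 145, 17, 19, 79 and 17. Protein-coding genes were 8011 of the 8898 with a value of at least 5 in any library. Among genes past the rule they were fewer, with 60 of 111 higher and 35 of 65 lower in MiwiΔIns. Median and upper quartile scaling, removal of mitochondrial and top 50 genes, and GC and length correction (chosen after seeing the data) kept every count within 1.5 times; the cause of the changed splits under these was not tested.

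Of 50 named-gene ratios past the rule, 24 lost it with a pseudocount of 5 and 6 with the GC and length correction, and 0 reversed in any alternative. Of 12 list medians that stood apart, 11 did so with the GC and length correction and 10 with median scaling. Others came to stand apart, for totals of 17 with the correction and 14 with a pseudocount of 5. With the correction these were late spermiogenesis in MiwiΔIns (percentile 99.07), ribosomal protein genes in MiwiR371W (99.83) and, between the mutants, late spermiogenesis (1.62), the unfolded protein response (98.11), mRNA decay (97.76) and mitochondrial mRNAs (98.56). With a pseudocount of 5 they were, in MiwiR371W, Sertoli markers (1.5) and mRNA decay (97.64), and between the mutants the unfolded protein response (97.57). Sertoli markers in MiwiΔIns reached percentile 5.40 with a pseudocount of 5 and 2.99, 3.22 and 3.24 in the 3 rescalings. Translation regulators in MiwiR371W lay on the upper limit with median scaling and at percentile 80.65 with the correction, and immediate early genes in MiwiR371W at 96.09 for members with a mean of at least 5. Mitochondrial mRNAs have no value without mitochondrial genes. Depth limits low genes most, with about 55 fragments at a value of 5 in 1 kb in MiwiR371W.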

Other observations

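Gene classes that were not on the fixed lists separated the mutants, and these groups and the test on them were chosen after the data were seen. Genes still carrying RIKEN clone names of testis cDNA series, such as 1700023C21Rik and 4930555K19Rik, had a median log2 ratio of 0.26 in MiwiΔIns and −0.15 in MiwiR371W against wild type (542 genes with a mean of at least 5). Past the size rule, 16 were higher and 0 lower in MiwiΔIns, and 8 were higher and 27 lower in MiwiR371W. Between the mutants directly, 434 of 542 were lower in sign in MiwiR371W, with a median of −0.39. Both medians against wild type lay outside 1000 random lists matched on expression, at percentiles 100 and 0. With the GC and length trend removed (539 genes) they were 0.14 and −0.17, still at percentiles 100 and 0.

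Antisense genes had a median of 0.22 in MiwiΔIns, −0.15 in MiwiR371W and −0.38 between the mutants (229 genes). For lincRNA genes the medians were 0.18, 0.00 and −0.21 (214 genes), for pseudogenes 0.14, −0.06 and −0.16 (177 genes), and for processed transcripts 0.21, −0.04 and −0.24 (114 genes). After removal of the trend, the MiwiΔIns medians were 0.09 for antisense genes, 0.07 for lincRNA genes, 0.05 for pseudogenes and 0.13 for processed transcripts, still outside the limits (percentiles 100, 99.9, 98.8 and 100). In MiwiR371W they were −0.16, −0.04, −0.09 and −0.03, the last no longer outside the limits (percentile 6.0). Those between the mutants were −0.28 for antisense genes, −0.11 for lincRNA genes and for processed transcripts, and −0.01 for pseudogenes, the last no longer outside the limits (percentile 6.4). Antisense values cannot be separated from their sense partners without strand information.

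Of the chromatin-packing proteins, Tnp1 was at 2626 in wild type, 4861 in MiwiΔIns and 2811 in MiwiR371W, while Prm2 was at 3503, 4540 and 4645. The log2 ratios to wild type were 0.89 and 0.10 for Tnp1 and 0.37 and 0.41 for Prm2, none past the rule. These genes were chosen after their values were seen.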
